A study of Mus musculus with 4 samples.

How the data were processed

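RNA from ATDC5 cells was profiled on 4 Affymetrix mouse expression arrays, 2 after transfection with a scrambled duplex and 2 after transfection with a Chadl duplex. Per the labels' protocols, cells received 30 nM of a 27-mer RNA duplex with a lipid reagent, and after 16 h the medium was changed to differentiation medium. RNA was taken at 5 days and labelled with biotin by in vitro transcription from the polyadenylated end. The labels report 1 effective Chadl duplex and give a 25-nucleotide sequence for it, and no position in the genome was derived for it here. Samples were grouped by their titles, and replicate numbers are those of the titles.

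The deposited values are log2 signals per probe set, normalized by the authors with RMA, per the submitters' processing notes. RMA subtracts background, makes the arrays' probe distributions alike and summarises the probes of a probe set, so differences in total RNA between samples are removed and the change of dim genes is compressed. Its software and version are not given in the sources used here. The base of the logarithm was read from the range of the values, 2.19 to 12.72. No per-sample columns were left unused. The precision is limited by the number of arrays, 2 per group.

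The table held 45141 probe sets, of which 104 array controls were left out of the gene tests and 45037 were tested. By the platform annotation used, which can be old, 28898 probe sets carried 1 gene symbol, 551 several and 15692, array controls included, none. Gene identifiers matched a table of mouse genes of assembly GRCm38.p6, used only for names, for 28689 probe sets, and 0 symbols were updated. Each of 17097 genes was represented by the probe set with the highest mean signal among those with 1 symbol, and 7180 genes had more than 1 probe set. Where other probe sets of a named gene differed in sign, the text says so. Genes carried only by probe sets with several symbols or none were not analysed here.

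Knockdown was compared with control with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), with 2 residual and 4.45 prior degrees of freedom, Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, with no further normalization and no filter on dim genes. All p-values are two-sided and come from this model or from the list tests, and intervals are at the 95% level. Confidence intervals and SEs are those of the moderated fit. Before the data were examined, the samples, this design, 29 gene lists and the alternatives were fixed. Lists were tested with camera at a preset correlation between genes of 0.01, with adjustment over the 29 lists. Other list tests were camera with the correlation estimated from the data, which has only the 2 residual degrees of freedom, and fry, which asks whether a list's genes move one way on balance and compares no list with other genes. "Adjusted over the list alone" means Benjamini-Hochberg adjustment over the members of that list.

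The rule for named genes took Chadl, then up to 12 passing genes in each direction whose arrays do not overlap between groups and whose mean is at or above the median of all genes (4.86), skipping predicted genes and clones. Where fewer passed, it took the genes with the smallest unadjusted p under the same rule up to 6 in each direction. From each list it took up to 4 passing members or, where none passed, the 2 brightest. Members passing adjusted over their list alone were added to these, which gave 81 genes. A further 35 genes were named after their values were seen, and the text says so where they appear.

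The limma step was tested on 20 simulated sets of 17097 genes with 200 changed genes and 2 arrays per group, with spreads drawn independently from limma's fitted prior. It recovered 41.9% of genes changed 1.41-fold, 96.3% of those changed 2-fold and 99.9% of those changed 4-fold, and called 8.4 unchanged genes on average. A list of 40 genes shifted by 0.2 was called in 20 of 20 sets, and an unshifted list in 0. The simulated genes were independent, while list members on real arrays can move together. The simulated groups also had equal spread. On the real arrays the SD of the knockdown pair's difference was 2.63 times that of the controls, among genes at or above the median level. The recovery shares therefore do not carry over to these arrays.

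Alternatives were quantile normalization across arrays, centring each array on its median, leaving out genes below the 40th percentile of mean signal, the mean of all probe sets of a gene, eBayes without the trend, robust eBayes, the replicate number as a block, and leaving out each array in turn. For the number of changed genes they also included a 1.5-fold minimum, an adjusted p of 0.1, all probe sets, and limma's treat with a minimum fold of 1.2. Camera has no robust option, so for that alternative cameraPR was run on the moderated statistics of the robust fit. Random lists matched on mean signal (10000 draws) describe where a list's median lies in each array, and hold unrelated genes, so their range is too narrow for lists whose members move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.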

Results

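Gene expression was measured in ATDC5 cells, a mouse chondrogenic cell line that forms cartilage-like matrix when placed in differentiation medium. Cells were transfected with a double-stranded RNA against Chadl or with a scrambled control duplex, and RNA was profiled after 5 days of differentiation. Chadl encodes chondroadherin-like, a protein with leucine-rich repeats related to the small leucine-rich proteoglycans of cartilage. There were 2 control arrays and 2 Chadl knockdown arrays, 4 in all, each read as log2 signal per probe set after RMA. Median signal over all probe sets was 4.24 and 4.25 in control 1 and control 2, and 4.24 and 4.25 in knockdown 1 and knockdown 2. The labels call the arrays biological replicates without saying whether cultures were separate, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value below, and the design allows a single comparison, knockdown against control.

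The targeted gene was lower in both knockdown arrays. Chadl, read by 1 probe set, had a log2 signal of 4.91 and 4.84 in the controls and of 4.29 and 4.64 in knockdown 1 and knockdown 2. The mean difference was -0.41 (SE 0.12, 95% confidence interval -0.71 to -0.11), a 1.32-fold lower signal. Knockdown 1 lay 1.49-fold and knockdown 2 lay 1.18-fold below the control mean. The gene's signal was at the 47.1th percentile of all genes. Array signal can understate fold changes of dim genes, and whether it did so for Chadl was not tested. The difference did not pass the test over all genes (unadjusted p = 0.0158, adjusted p = 0.728, limma). Without knockdown 2 the log2 difference was -0.58, and without knockdown 1 it was -0.23. The 25-nucleotide sequence given for the duplex that the labels report as effective against Chadl is ACAAGGUAGAGAAACAAAGAGACCA.

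No gene passed the test over all genes. Of 17097 genes, 0 passed an adjusted p of 0.05 in limma, with the lowest adjusted p, 0.178, for Penk, the precursor of the enkephalin opioid peptides. Penk signal was 8.40 and 8.40 in the controls and 9.21 and 9.41 in the knockdowns, a 1.88-fold difference (log2 difference 0.91, SE 0.07). Among genes at or above the median level, the next by unadjusted p on the higher side were the interferon-induced Ifit3 (log2 difference 0.28), the Wnt agonist Rspo2 (0.76), the secreted matrix protein Cthrc1 (0.61), the surface sialomucin Cd34 (0.85) and the cytokine Il33 (0.58). On the lower side they were the ecto-nucleotidase Nt5e (-0.63), the adrenomedullin co-receptor Ramp2 (-0.46), the oxysterol hydroxylase Cyp39a1 (-0.51), the small leucine-rich proteoglycan Aspn (-0.34), the splicing regulator Tra2b (-0.45) and the chromatin remodeller Chd4 (-0.43). None of these 12 genes passed. Over all 45037 probe sets 1 passed, a probe set of Ramp2 with signals of 11.19 and 11.18 in the controls and 10.55 and 10.57 in the knockdowns (log2 difference -0.63, SE 0.03, adjusted p = 0.00481). A dim probe set of Ramp2 differed by 0.04 the other way, and 1 of 3 probe sets of Nt5e also had the opposite sign. At an unadjusted p of 0.05 there were 1141 genes, 710 higher and 431 lower in knockdown. With no effect and equal spread in both groups, 855 would be found. Both knockdown arrays lay above both controls for 3623 genes (21.2%) and below both for 2922 (17.1%). Chance gives 16.7% in each direction only where all arrays vary alike. Over all genes the SD of the knockdown pair's difference was 1.93 times that of the controls. Unequal spread raises the chance share, so these shares cannot be read as an excess over chance.

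Knockdown 1 stood further from the controls than knockdown 2. The SD of the log2 difference over genes was 0.10 between the 2 controls, 0.20 between control 1 and knockdown 1, 0.13 between control 1 and knockdown 2, and 0.20 between the knockdowns. Against control 1, 66 genes differed more than 2-fold in knockdown 1 and 9 in knockdown 2, and 0 did between the controls. Without knockdown 1 limma passed 561 genes (327 higher, 234 lower), and without knockdown 2 it passed 2584 (1528 higher, 1056 lower), with the lone knockdown array taken to vary like the controls. Many of the 116 genes named here were picked for a small p or a large change in these same arrays. How many of them pass in these 2 fits is therefore no support for them. Mean differences over 2-fold with no overlap of the groups were seen for 13 genes, of which Ibsp was also named by the rule and the other 12 only after their values were seen. The 4 higher ones were Igfbp3 (log2 difference 1.22), Plac1 (1.22), Cacna2d3 (1.06) and Prl2c2 (1.03). The 9 lower ones were Ibsp (-2.13), Panx3 (-1.68), Tmem119 (-1.34), Cadm1 (-1.29), Npnt (-1.26), Smpd3 (-1.15), Slc8a3 (-1.11), Fam107a (-1.05) and C1qtnf3 (-1.01). For Npnt 1 of 5 probe sets had the opposite sign. Most of these differences lay in knockdown 1. In knockdown 2 only Ibsp (-1.14) was more than 2-fold from the control mean, and the others lay between -0.59 (Fam107a) and 0.57 (Igfbp3).

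**Figure D1:**
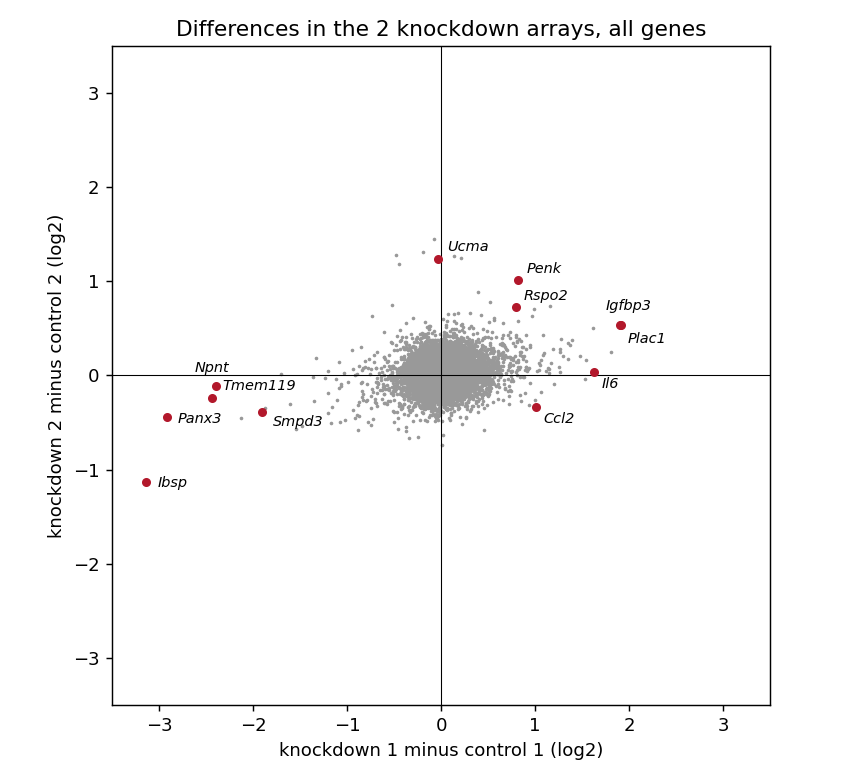
Each point is 1 of 17097 genes, placed by its log2 difference in knockdown 1 from control 1 (horizontal) and in knockdown 2 from control 2 (vertical), with named genes in red. The cloud is wider along the knockdown 1 axis, and Ibsp lies far below 0 on both axes while Il6 lies to the right with little difference in knockdown 2.

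The list of chondrocyte hypertrophy and mineralization genes had a median below control in both knockdown arrays. Ibsp, the bone sialoprotein of mineralizing matrix, had signals of 10.15 and 10.15 in the controls and of 7.02 and 9.01 in the knockdowns, 8.77-fold and 2.2-fold below the control mean (log2 difference -2.13, SE 0.56, unadjusted p = 0.00757, adjusted p = 0.694). The channel gene Panx3 read 9.35 and 9.33 against 6.43 and 8.89, the parathyroid hormone receptor gene Pth1r 9.05 and 9.09 against 7.70 and 8.82, and the transcription factor gene Mef2c 7.43 and 7.42 against 6.24 and 7.02. These 3 were picked after their values were seen. Vegfa, the vascular growth factor gene, was 1.23-fold lower (log2 difference -0.30), with 1 of its 2 probe sets of opposite sign. The other bright member, the pyrophosphate transporter gene Ank, read 9.68 and 9.68 against 9.22 and 9.95. Col10a1, the hypertrophic collagen, was dim and level at 3.58 and 3.59 against 3.52 and 3.65. The hedgehog ligand gene Ihh differed by -0.01, the collagenase gene Mmp13 by 0.18 and the endopeptidase gene Phex by 0.32, these 4 also picked after their values were seen. Mmp13 and Phex were higher in knockdown 1 only. Col10a1 and Mmp13 lay at the 16.4th and 8.26th percentiles of signal, where a lower level could hardly be seen. Ihh lay at the 33.2th percentile, and whether a fall could be seen at its level was not tested. The small difference thus says little about Ihh. Dmp1 of the same list, picked in the same way, lay at the 29.4th and read 4.36 and 4.23 against 3.16 and 4.04. Its percentile includes the lower knockdown signals, and both its control signals were above those of Ihh. Dmp1 therefore does not show that a fall of Ihh could be seen. Of 17 members measured, 10 had both knockdown arrays below both controls and 0 had both above. None passed over all genes, 1 (Vegfa) passed adjusted over the list alone, and 7 were lower at an unadjusted p of 0.05. The median difference was -0.30, with -0.47 in knockdown 1 and -0.16 in knockdown 2. In camera with the preset correlation the list lay below other genes (adjusted p = 3.03e-05), and the call was lost with an estimated correlation (adjusted p = 0.491) and with fry (adjusted p = 0.285).

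The osteoblast marker list, which shares 5 genes with the hypertrophy list, also lay lower. Of its 14 measured members, 8 had both knockdown arrays below both controls, 4 were lower at an unadjusted p of 0.05, and 0 passed over all genes or adjusted over the list alone. Its median was -0.12, with -0.17 in knockdown 1 and -0.05 in knockdown 2, the latter just within the central 95% of random lists matched on signal (-0.05 to 0.08). It passed in camera and in neither of the other list tests (camera adjusted p = 0.000613, adjusted p = 0.491 with an estimated correlation, adjusted p = 0.425 with fry). The sphingomyelinase gene Smpd3 read 7.0 and 7.07 in the controls against 5.10 and 6.69. Osteocalcin (Bglap) read 6.80 and 6.82 against 5.68 and 6.78, osterix (Sp7) 8.45 and 8.38 against 7.60 and 8.30, and the matrix phosphoprotein gene Dmp1 4.36 and 4.23 against 3.16 and 4.04. These 4 were picked after their values were seen, and most of their difference lay in knockdown 1. Col1a1, the chain of the main bone collagen, differed by -0.14 (SE 0.05), alike in both arrays. Members of a list that the annotation used does not name were not analysed here.

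Cartilage matrix genes as a group did not pass. The 23 members had a median difference of -0.03, with -0.07 in knockdown 1 and 0.05 in knockdown 2 (camera adjusted p = 0.325), and 0 passed over all genes or adjusted over the list alone. At an unadjusted p of 0.05, 1 was higher and 2 were lower. The members' median percentile of signal was 37.8, and Chad lay at the 19.3th, levels at which array signal can understate fold changes. The small median difference thus says little about the dim members. Type II collagen (Col2a1) read 9.01 and 9.08 in the controls and 8.23 and 9.17 in the knockdowns, a mean difference of -0.35 (SE 0.27) that was of opposite sign in the 2 knockdown arrays. Col11a1, a chain of type XI collagen, was 1.11-fold higher (log2 difference 0.15, SE 0.05). Of members picked after their values were seen, Col11a2 differed by -0.36 and the link protein gene Hapln1 by -0.41, Col9a1 by -0.26 with its 2 probe sets of opposite sign, aggrecan (Acan) by -0.01 and chondroadherin (Chad) by -0.09. Ucma, which encodes a cartilage matrix-associated protein, read 5.48 and 5.58 against 5.45 and 6.82, and was picked in the same way. Without knockdown 1 the list's direction turned upward (adjusted p = 0.0693), and without knockdown 2 it lay lower and passed (adjusted p = 0.00833).

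Chondrogenic transcription factors and signals lay slightly lower as a list of 17, with a median of -0.07. The list shares 2 genes, Ihh and Pth1r, with the hypertrophy list. The call (camera adjusted p = 0.0455) was lost with an estimated correlation (adjusted p = 0.491), with fry (adjusted p = 0.283), without control 1 (adjusted p = 0.0592) and without control 2 (adjusted p = 0.0726). It was also lost with the mean of probe sets (adjusted p = 0.108), without the trend (adjusted p = 0.0549) and with robust eBayes (adjusted p = 0.0601). At an unadjusted p of 0.05, 5 members were lower and 1 was higher, and 0 passed over all genes or adjusted over the list alone. The forkhead factor gene Foxc1 differed by 0.10 and the ubiquitin ligase gene Wwp2 by -0.10, with 1 of 6 Wwp2 probe sets of opposite sign. Picked after their values were seen, Sox9, the master factor of chondrogenesis, read 7.52 and 7.47 against 7.50 and 7.49, and Fgfr3 6.72 and 6.51 against 5.64 and 6.38. Among small leucine-rich proteoglycans, the family nearest to Chadl, Lum (-0.69) and Aspn (-0.34) passed adjusted over the list alone and 0 of 15 passed over all genes. Bgn differed by 0.08 and Ogn by 0.28, the latter by 0.48 in knockdown 1 and 0.07 in knockdown 2. Of the 15 members of this family, 4 were lower and 1 was higher at an unadjusted p of 0.05 in limma. The list as a whole did not pass in camera (median -0.04, adjusted p = 0.169).

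**Figure D2:**
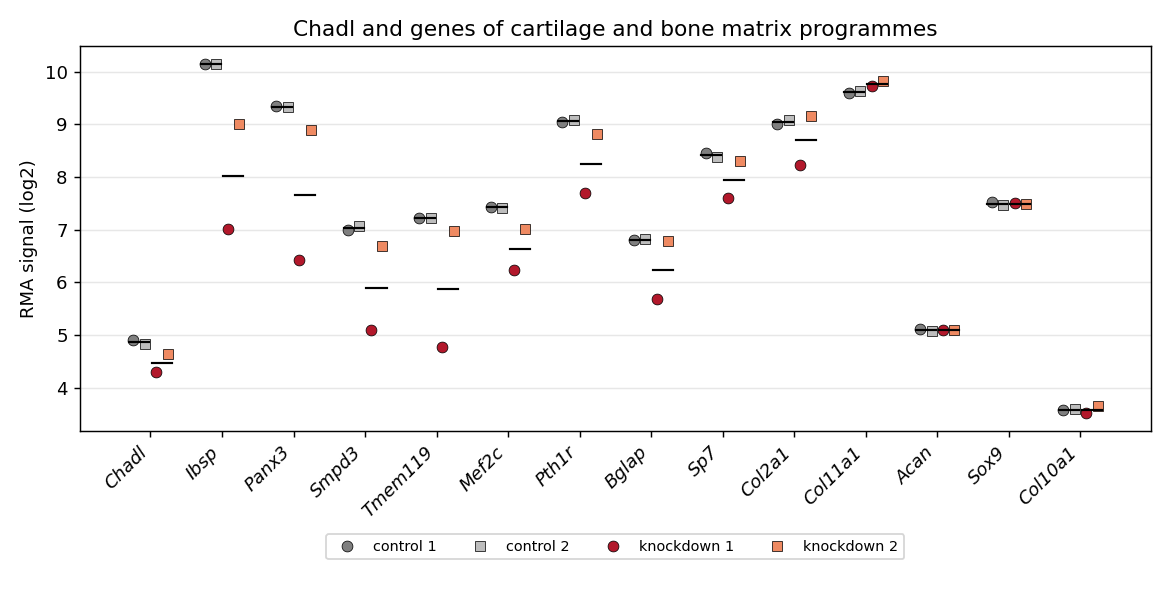
RMA signal (log2) of Chadl and 13 genes of cartilage and bone matrix programmes in each of the 4 arrays, with horizontal bars at the mean of each group of 2. Ibsp reads 10.15 in both controls and 7.02 and 9.01 in the knockdowns, while Sox9, Acan and Col10a1 read alike in all arrays.

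Genes of the interferon and double-stranded RNA response lay higher in both knockdown arrays. Of 38 members measured, 31 had both knockdown arrays above both controls and 0 had both below, 16 were higher at an unadjusted p of 0.05, and 0 passed over all genes. Adjusted over the list alone 3 passed, which were Ifit1, whose product binds viral RNA, Ifit3, and Ddx58, which encodes the RNA sensor RIG-I. Ifit3 read 10.98 and 11.01 in the controls and 11.27 and 11.28 in the knockdowns, 1.21-fold higher (log2 difference 0.28, SE 0.03, unadjusted p = 4.6e-05, adjusted p = 0.3). Ifit1 was 1.21-fold and Ddx58 1.16-fold higher, and 1 of 3 Ddx58 probe sets had the opposite sign. The bright member Xaf1 differed by 0.06, also with 1 of 2 probe sets of opposite sign. The exonuclease gene Isg20 read 8.70 and 8.67 against 9.32 and 8.89, Irf1 7.83 and 7.90 against 8.66 and 7.97, and Cxcl10 8.59 and 8.62 against 9.32 and 8.72, all 3 picked after their values were seen. The median difference was 0.20, with 0.30 in knockdown 1 and 0.10 in knockdown 2. Camera with the preset correlation gave an adjusted p of 1.34e-15, and the call was lost with an estimated correlation (adjusted p = 0.491) and with fry (adjusted p = 0.397).

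Inflammatory cytokines and NF-kB targets lay higher in knockdown 1. The 26 members had a median difference of 0.17, with 0.30 in knockdown 1 and -0.01 in knockdown 2. Of them 5 were higher and 0 lower at an unadjusted p of 0.05, 0 passed over all genes, and 1 passed adjusted over the list alone. It was Cxcl5, a neutrophil chemokine gene, which differed by 0.61. Cxcl5 was dim, at the 36th percentile of signal, and read 3.82 and 3.88 in the controls against 4.62 and 4.31. Il6 read 5.40 and 5.30 in the controls and 7.03 and 5.34 in the knockdowns, and Ccl2 6.52 and 6.54 against 7.53 and 6.21, both picked after their values were seen. Of the bright members, the inhibitor gene Nfkbia read 7.54 and 7.48 against 7.99 and 7.50, and Sod2 differed by -0.07 with 1 of 4 probe sets of opposite sign. The camera call (adjusted p = 0.000319) was lost without knockdown 1 (adjusted p = 0.962), with an estimated correlation (adjusted p = 0.674) and with fry (adjusted p = 0.534).

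Cell cycle genes parted between the knockdown arrays. The 34 members had a median of -0.16 in knockdown 1 and 0.06 in knockdown 2, and of -0.04 over both (camera adjusted p = 0.0211). The direction turned upward without knockdown 1 (adjusted p = 0.017), and the call was lost without control 1 (adjusted p = 0.0941), with an estimated correlation (adjusted p = 0.749) and with fry (adjusted p = 0.764). The replication genes Pcna and Cdt1 differed by -0.03 and -0.05, and 1 of 3 Cdt1 probe sets had the opposite sign. None of the list passed over all genes or adjusted over the list alone.

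**Figure D3:**
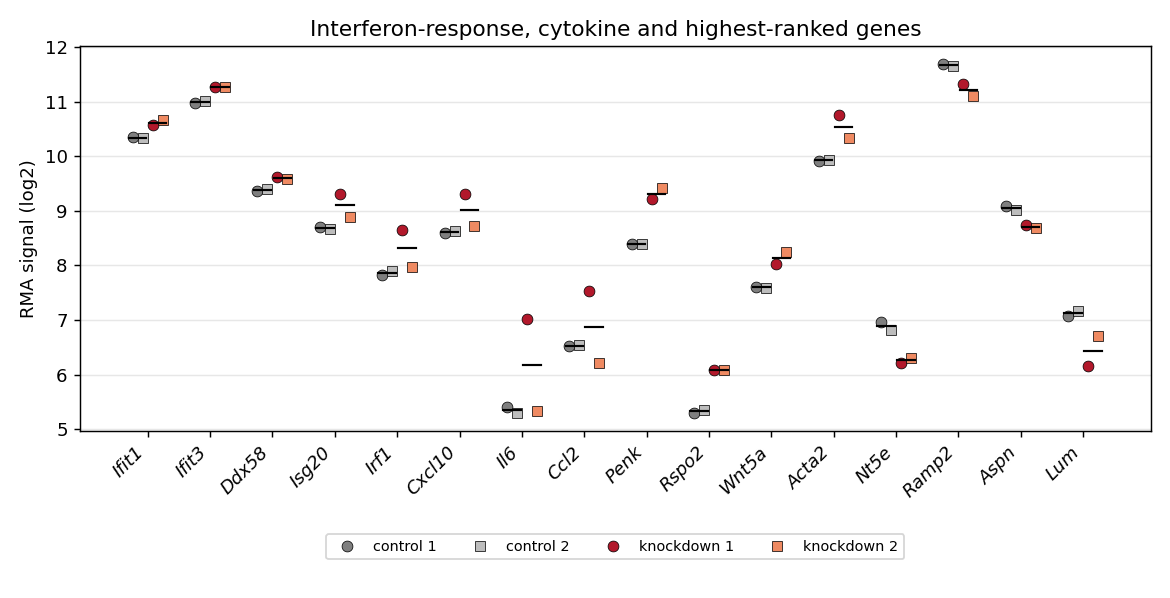
RMA signal (log2) of interferon-response and cytokine genes and of genes ranked high by p or within a list, in each of the 4 arrays, with horizontal bars at the mean of each group of 2. Il6 (7.03 and 5.34) and Ccl2 (7.53 and 6.21) part between the knockdowns, while genes ranked by p were selected in part for a small spread within groups.

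A further 5 lists passed in camera with small medians, and each call was lost with an estimated correlation (adjusted p = 0.491 for each). In these lists 0 members passed over all genes. Ribosomal protein genes (29 members) had a median of -0.02 (adjusted p = 3.03e-05, adjusted p = 0.115 with fry), with 18 below both controls in both arrays. Their median in knockdown 1 (-0.02) lay within the central 95% of random lists matched on signal (-0.05 to 0.02), in knockdown 2 (-0.03) below that range (-0.02 to 0.03), and the bright Rps6 and Rps2 each differed by -0.01 and had 1 of 3 probe sets of opposite sign. Unfolded protein response genes (29 members) had a median of -0.05 (adjusted p = 0.0211), and the chaperone genes Canx and Hsp90b1 differed by -0.01 and -0.0043. That call was lost with fry (adjusted p = 0.125), without control 1 (adjusted p = 0.0836), without control 2 (adjusted p = 0.0726) and without knockdown 2 (adjusted p = 0.213). Hedgehog signalling genes (14 members) had a median of 0.07 (adjusted p = 0.0211). Gli2, a transcription factor of the pathway, differed by 0.51 and passed adjusted over the list alone, the receptor gene Ptch1 differed by 0.24 and Smo by 0.03. The hedgehog call was lost without control 1 (adjusted p = 0.0845) and with fry (adjusted p = 0.0876). Matrix proteases and inhibitors (27 members) had a median of 0.07 (adjusted p = 0.0269). The inhibitor gene Timp2 differed by 0.34 and passed adjusted over the list alone, but 3 of its 5 probe sets had the opposite sign, and Timp3 differed by 0.10. The protease call was lost with fry (adjusted p = 0.115), with the mean of probe sets (adjusted p = 0.0913) and without any 1 array (adjusted p = 0.0701 and 0.064 without control 1 and control 2, 0.111 and 0.0524 without knockdown 1 and knockdown 2). Tendon and ligament genes (10 members) had a median of -0.07 (adjusted p = 0.0455), and Mkx (-0.28), Egr1 (-0.39) and Egr2 (-0.41), all transcription factor genes, passed adjusted over the list alone. Egr1 and Egr2 are also in the immediate early and stress list, so they are not separate evidence in the 2 lists. The matrix gene Tnc differed by -0.31, with -0.55 in knockdown 1 and -0.06 in knockdown 2. The tendon call was lost with fry (adjusted p = 0.274), with the mean of probe sets (adjusted p = 0.0913), with robust eBayes (adjusted p = 0.0568), without control 2 (adjusted p = 0.221) and without knockdown 2 (adjusted p = 0.0978).

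Several signalling and marker lists did not pass, though single members stood out. In Wnt signalling (33 members, adjusted p = 0.775) the ligand gene Wnt5a (0.53), the receptor gene Fzd2 (0.39) and Rspo2 (0.76) were higher and passed adjusted over the list alone, while Ctnnb1 differed by -0.07 and Ccn4 by -0.21. The list's median was -0.01, its mean 0.01 and its test upward. In BMP and TGF-beta signalling (36 members, adjusted p = 0.239) the activin antagonist Fst (0.70) passed adjusted over the list alone, Tgfbi differed by 0.25 and Bmp4 by 0.05. Smooth muscle actin (Acta2, 0.61, with 1 of 2 probe sets of opposite sign) passed in the same way among 19 muscle markers (adjusted p = 0.166), and Tnnc1 differed by 0.42. Among 27 immediate early and stress genes (adjusted p = 0.187) Egr1 and Egr2 were lower and the chaperone gene Hsph1 (0.22) higher, each passing adjusted over the list alone, while Hspa8 differed by -0.09 and Hspa1b by -0.06. In all these lists 0 members passed over all genes. The BMP list passed without knockdown 2 (adjusted p = 0.00204).

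Matrix synthesis and metabolism lists also did not pass, with 0 members passing over all genes or adjusted over the list alone. Proteoglycan and glycosaminoglycan synthesis (26 members) gave an adjusted p of 0.187, with Ugdh at 0.11 and Bpnt2 at -0.09. Fibroblast and fibrillar collagen matrix (24 members) gave 0.272, with Sparc at -0.04 and Col3a1 at -0.02, and collagen folding (21 members) gave 0.444, with P4hb at 0.04 and Pcolce at 0.06. Cholesterol synthesis (19 members) gave 0.464, with Ebp at -0.04 and Cyp51 at -0.06. Glycolysis and hypoxia (26 members) gave 0.457, with Ldha at -0.11 and Pgk1 at -0.0003, and oxidative phosphorylation (33 members) gave 0.325, with Cox4i1 at 0.02 and Atp5h at -0.04. Of these, glycosaminoglycan synthesis (adjusted p = 0.0276), glycolysis (0.0259) and oxidative phosphorylation (0.0057) lay lower and passed without knockdown 2, and fibroblast matrix (0.0153) and cholesterol synthesis (0.0437) lay lower and passed without knockdown 1. Integrins and focal adhesion (24 members) gave 0.859, with Vcl at -0.10 and Itgav at 0.06. The p53 targets (20 members) gave 0.54, with Ddit4 at -0.11 and Ccng1 at -0.04.

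Adipocyte, endothelial and blood, and neural and epithelial markers did not pass either, nor did RNA interference genes, again with 0 members passing over all genes or adjusted over the list alone. Adipocyte markers (18 members) gave an adjusted p of 0.615, with Scd1 at -0.10 and Fasn at 0.0031. Endothelial and blood cell markers (15 members) gave 0.615, with Cd14 at -0.11 and Hba-a1 at -0.09, and here the median was -0.01, the mean 0.0016 and the test downward. Neural and epithelial markers (17 members) gave 0.859, with Epcam at 0.01 and Syp at 0.08. Genes of the RNA interference machinery (14 members), through which duplexes act, gave 0.665, with Tnrc6a at -0.00098 and Ago2 at 0.06. Among the genes of this and the preceding paragraph, Col3a1, Vcl, Itgav, Ccng1, Cyp51, Hba-a1, Tnrc6a and Ago2 had probe sets of opposite sign.

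**Figure D4:**
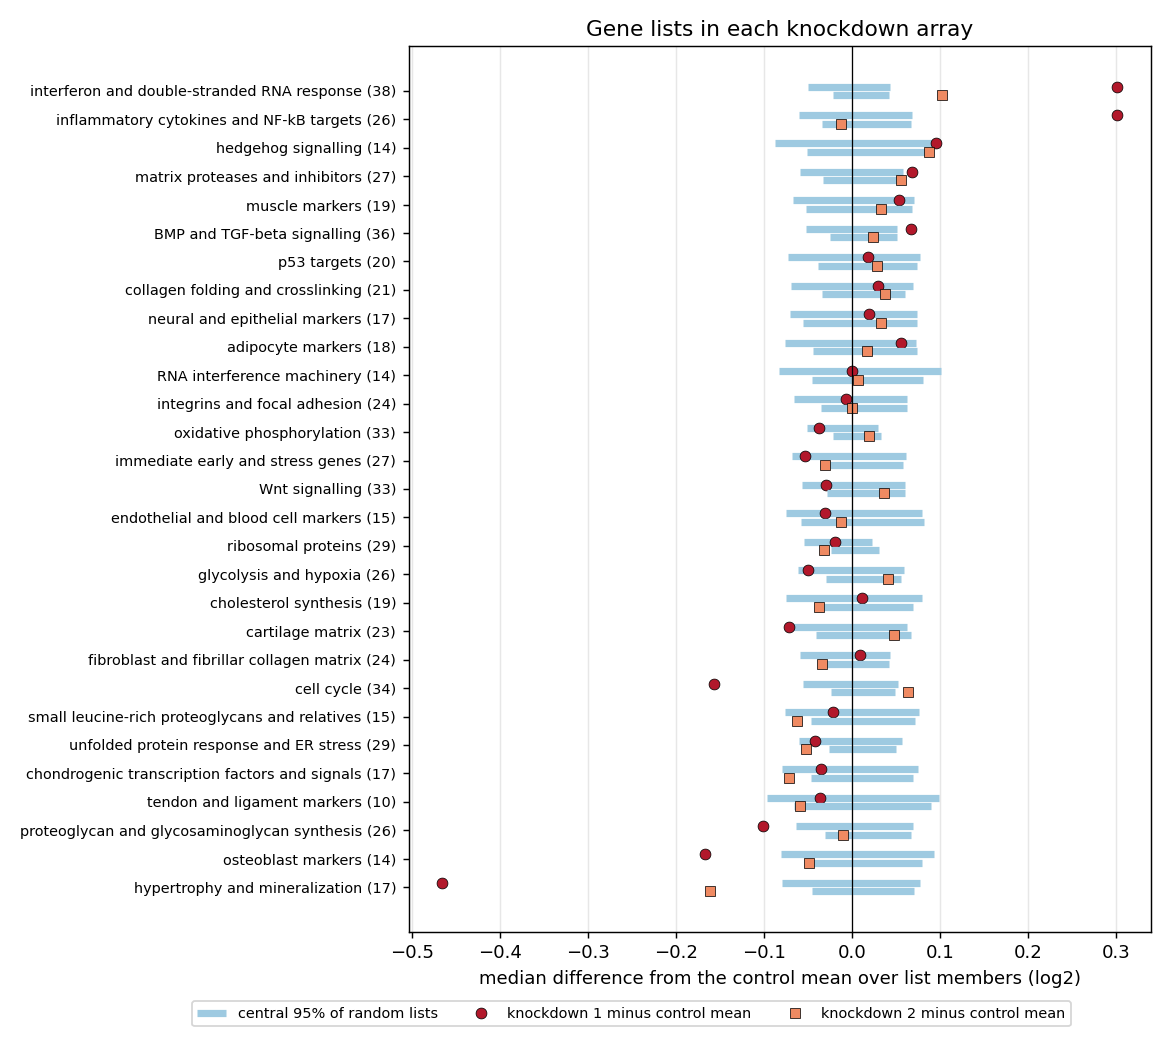
Median log2 difference from the control mean over the members of each of 29 gene lists (number of members measured in parentheses), for knockdown 1 (circles) and knockdown 2 (squares), with blue bars for the central 95% of 10000 random lists matched on mean signal. The hypertrophy list lies below its bars and the interferon list above its bars in both arrays, and the NF-kB list lies above them in knockdown 1. Random lists hold unrelated genes, so the bars are too narrow for lists whose members move together.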

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

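No gene passed an adjusted p of 0.05 in limma under quantile normalization, centring, leaving out dim genes, the mean of probe sets, eBayes without the trend, robust eBayes, a 1.5-fold minimum, treat or an adjusted p of 0.1, against 1141 genes at an unadjusted p of 0.05. Over all probe sets 1 passed. The 2 groups share replicate numbers, which the labels do not tie to a day or culture. With the replicate number as a block 0 genes passed and 1048 had an unadjusted p under 0.05, and same-numbered deviations correlated at -0.0041. No list call changed under that block. Chadl stayed lower and not past the threshold under every setting that kept all 4 arrays, and its log2 difference ranged from -0.58 to -0.23 over the 4 fits without 1 array. Those fits, in which a lone array is taken to vary like the other group, gave 0 to 2584 changed genes and 6 to 13 lists of 29, against 11 with all arrays.

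With an estimated correlation 0 lists passed, and with fry 0 passed. The hypertrophy list had an adjusted p of 0.491 and 0.285 in these. With an estimated correlation camera has only the 2 residual degrees of freedom, and its lowest unadjusted p of any list was 0.0838. The hedgehog, unfolded protein, protease and chondrogenic calls were lost although their estimates were below 0. The estimates were above the preset 0.01 for the cell cycle (0.721), interferon (0.627), inflammatory (0.4), osteoblast (0.165), hypertrophy (0.116), ribosomal (0.0627) and tendon (0.0148) lists. What correlation and the degrees of freedom each took from these calls was not separated. The fry test asks another question. Its mixed form, which counts change in either direction and compares a list with no other genes, passed 7 lists. They were tendon (adjusted p = 0.0111), small leucine-rich proteoglycan, unfolded protein and Wnt (0.025 each), and glycolysis, immediate early and RNA interference (0.0301 each). The hypertrophy list had 0.301 and the interferon list 0.294 in it. In the 7 settings other than these 2 and leaving out arrays, the hypertrophy list kept its call and direction and the cartilage list stayed unpassed, with adjusted p up to 0.757. Of 261 list results in the 9 settings, 227 kept direction and side of the threshold, 28 lost the call and 6 reversed. In all, 6 of the 28 came from settings other than the estimated correlation and fry, among the chondrogenic, protease and tendon lists. The 6 reversals were all of uncalled lists. The neural list had an adjusted p of 0.911 with dim genes left out. With the mean of probe sets it had 0.963, integrins 0.996, Wnt signalling 0.921 and endothelial markers 0.921. With fry integrins had 0.739.

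Of 805 results for the 116 named genes in these settings, 0 passed and 14 reversed, all from main differences of 0.09 or less. With quantile normalization Canx was 0.0045, Hsp90b1 0.012 and Pgk1 0.017. With centring Pgk1 was 0.0033, Tnrc6a 0.0026 and Sox9 0.00099. With the mean of probe sets Col3a1 was 0.024, Itgav -0.0015, Ccng1 0.018, Xaf1 -0.10, Rps6 0.0041, Hba-a1 0.088, Tnrc6a 0.038 and Sox9 0.028. In the last setting other probe sets of these genes had the opposite sign. The cause of the other reversals was not tested. The median difference of all genes lay between 0.0043 and 0.01 in these settings.

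Leaving out arrays turned the sign of 36 named genes, with these ranges of the log2 difference: Col2a1 -0.82 to 0.12, Ank -0.47 to 0.27, Col3a1 -0.091 to 0.056, Timp3 -0.13 to 0.32, Ddit4 -0.27 to 0.063, Ccng1 -0.086 to 0.0038, Nfkbia -0.013 to 0.48, Canx -0.045 to 0.017, Hsp90b1 -0.051 to 0.042, Ebp -0.11 to 0.035, Ldha -0.22 to 0.0043, Pgk1 -0.038 to 0.037, Cox4i1 -0.00025 to 0.046, Atp5h -0.12 to 0.045, Rps6 -0.018 to 0.0060, Rps2 -0.016 to 0.0034, Bmp4 -0.12 to 0.23, Ctnnb1 -0.17 to 0.022, Ccn4 -0.50 to 0.084, Smo -0.032 to 0.088, Fasn -0.044 to 0.050, Cd14 -0.33 to 0.12, Epcam -0.040 to 0.060, Syp -0.051 to 0.21, Hspa1b -0.28 to 0.15, Tnrc6a -0.077 to 0.075, Col9a1 -0.68 to 0.17, Col10a1 -0.068 to 0.068, Acan -0.031 to 0.0080, Sox9 -0.026 to 0.021, Il6 -0.012 to 1.67, Ccl2 -0.32 to 1.00, Ucma -0.084 to 1.29, Ihh -0.14 to 0.12, Mmp13 -0.027 to 0.38, Phex -0.22 to 0.86. Lists that turned had these ranges of adjusted p: cartilage matrix 0.00833 to 0.463, proteoglycan and glycosaminoglycan synthesis 0.0276 to 0.962, cell cycle 1.56e-10 to 0.0941, cholesterol synthesis 0.0437 to 0.824, glycolysis and hypoxia 0.0259 to 0.537, oxidative phosphorylation 0.0057 to 0.52, BMP and TGF-beta signalling 0.00204 to 0.596, Wnt signalling 0.369 to 0.934, adipocyte markers 0.227 to 0.683, endothelial and blood cell markers 0.52 to 0.962, neural and epithelial markers 0.511 to 0.962, RNA interference machinery 0.393 to 0.962. The cause was not tested beyond the difference between the knockdown arrays. Signal near background limits Chadl, Dmp1, Col10a1 and other dim genes.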

Other observations

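All tests of explanations in this part were chosen after the results were seen, and the genes of the next paragraph were picked in the same way.

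Genes outside the lists also differed from control. Igfbp3, an insulin-like growth factor binding protein, read 7.42 and 7.47 in the controls and 9.32 and 8.02 in the knockdowns. The placenta-enriched Plac1 read 5.41 and 5.38 against 7.32 and 5.91, and the prolactin family gene Prl2c2 4.04 and 4.03 against 5.84 and 4.28. The stromal chemokine gene Cxcl12 read 10.64 and 10.65 against 11.12 and 10.85. On the lower side, the osteoblast membrane protein gene Tmem119 read 7.22 and 7.21 against 4.78 and 6.98, the adhesion gene Cadm1 7.74 and 7.71 against 5.61 and 7.26, and the integrin ligand gene Npnt 6.40 and 6.24 against 4.01 and 6.12. None passed over all genes.

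The knockdown arrays differed from each other more than the controls did. Among the 8549 genes at or above the median level, the SD of the array difference for the knockdowns was 2.63 times that for the controls. This ratio was 2.65 for genes with a mean over 5 and 1.93 for all genes. For hybridization spikes the ratio was 1.15 (95% bootstrap interval 0.643 to 1.66, 18 probe sets) and for polyadenylated spikes carried through labelling 0.948 (0.624 to 1.64, 24 probe sets). These are 4 transcripts each and measure technical noise in 1 pair of arrays per group, so a difference in hybridization or labelling stays open. One response of differing strength may account for part of it: of the 100 genes lowest in knockdown 1 against control 1, 68% were lower in knockdown 2 against control 2, where 41.7% of all genes were and the central 95% of random sets ended at 51%, and of the 100 highest, 77% were higher, where 58.3% of all genes were and that range ended at 68%. The sizes 50, 100 and 200 were looked at, with 72, 68 and 63% on the lower side and 80, 77 and 78% on the higher side. Over the 8549 genes the 2 differences correlated only weakly (Pearson 0.217, Spearman 0.138), and cell cycle genes parted between the arrays. Random sets hold unrelated genes, so their range is too narrow where genes move together. The 3 array control probe sets for 18S ribosomal RNA read lower in both knockdown arrays, most in knockdown 2 (1 of them 9.68 and 9.64 against 9.50 and 9.19). What this reflects was not tested.

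The interferon list lay above control in both knockdown arrays. Its median in knockdown 2 was 0.10, and the central 95% of matched random lists spanned -0.02 to 0.04. Without knockdown 1 the list kept its call in camera (adjusted p = 9.42e-08), in a fit that takes the lone array to vary like the controls and members to correlate at the preset 0.01. Both comparisons rest on 1 array and treat members as nearly unrelated, while the list's estimated correlation was 0.627. The random range is therefore too narrow and the camera p too small for this list. Neither comparison can decide, and a shift in knockdown 1 alone stays open. With all arrays the call was lost with an estimated correlation (adjusted p = 0.491, a test with 2 residual degrees of freedom) and with fry (adjusted p = 0.397). The median of the inflammatory list in knockdown 2, -0.01, lay within the central 95% of its random lists (-0.03 to 0.07), and its call was lost without knockdown 1 (adjusted p = 0.962), which is what a shift resting on knockdown 1 would show. A response to the duplex itself, apart from lower Chadl, could raise interferon genes, and so could a lower level of Chadl. With 1 knockdown duplex these cannot be told apart.

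The hypertrophy list lay below control in both arrays. Its median in knockdown 2 was -0.16, and the central 95% of matched random lists spanned -0.05 to 0.07. Without knockdown 1 it kept its call (adjusted p = 3.76e-08), again at the preset correlation of 0.01 and with a lone array taken to vary like the controls. A shift in knockdown 1 alone stays open here too, since 1 array is left. With all arrays the call was lost in the same tests (adjusted p = 0.491 and 0.285). Of the 17 members 5 are shared with the osteoblast list, and the stage of the cells was not tested. An effect of the duplex on other transcripts stays open for the same reason as above.

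The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. The real split gave 1141 genes at an unadjusted p under 0.05 in limma, and the other splits gave 406 and 424. Both of these lie below the 855 that would be found with no effect and equal spread. In the other splits each group holds 1 control and 1 knockdown array, so the wider spread of the knockdown arrays enters both groups. Unequal spread can thus lower their counts, and the larger count of the real split is no support for an effect.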
